A study of Arabidopsis thaliana with 20 samples.

How the data were processed

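Cells were cut by laser capture from roots of Arabidopsis thaliana, accession Columbia, per the labels. Seedlings aged 3 weeks were inoculated with 1000 second-stage juveniles of the root-knot nematode Meloidogyne incognita, and roots were sectioned 21 days later. Giant cells are the enlarged feeding cells that this nematode induces in the root. Each giant cell sample held about 80 cells (5000000 square micrometres of section), and each control sample about 150 root cells (13000000 square micrometres) from regions of the same infested roots without nematodes. RNA was amplified with 1 of 2 kits of the same maker. For WT-Ovation Pico, RNA was first isolated with a spin-column kit, and for WT-Ovation One-Direct the captured cells went straight into lysis buffer. The amplification kit and the isolation step therefore cannot be told apart, and "kit" below stands for both together.

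The 20 arrays fall into 4 groups, control or giant cells with either kit, each of 3 biological samples. In each group 1 biological sample was split over 3 technical arrays, which gives 5 arrays per group. Technical arrays were averaged on the log2 scale and counted as 1 sample, so n = 3 per group throughout. The labels do not tie a sample to a plant, so p-values measure only the spread between these samples, some of which may share plants. For arrays, the number of samples limits the precision.

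The deposited values are linear signal intensity, 1 per probe set, for 22810 probe sets of an Affymetrix array. Per the submitters' processing notes, the authors used Affymetrix Expression Console and MAS5; the versions and the background correction are not given in the sources used here. The mean signal after trimming 2% at each end was about 500 on every array, as MAS5 scaling leaves it, and each array was rescaled to the common mean of these values. No array was identical to another. The 64 control probe sets were left out of the gene tests and used for array measures.

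From these values log2(signal + 16) was computed, so fold changes understate the change of dim probe sets. A probe set was kept if it lay above the median of its array in at least 3 of the 12 biological samples, which left 14652 of 22746. Means of the 4 groups were fitted to all 12 samples with limma (lmFit and eBayes), with 1 shared estimate of the spread per probe set. Tests were two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. The 7 contrasts were giant against control cells over both kits and in each kit, One-Direct against Pico over both cell types and in each, and the difference of the giant cell effect between kits. These tests, the alternatives and the gene lists were chosen before the data were examined, apart from those named as added.

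Gene names came from the array's annotation as given for these probe sets, updated through gene identifiers to a RefSeq table of assembly TAIR10.1, used for names and gene types only. Of the 22746 probe sets, 13513 carried 1 gene, 503 several and 8730 were not listed there, and among the kept ones these numbers were 8165, 373 and 6114. No gene was named from a probe set listed with several, although a probe set listed with 1 gene may still match others. Of 8082 genes with a kept probe set, 76 had more than 1, and 0 of these were called in opposite directions between giant and control cells; the probe set with the highest mean stood for the gene. Named genes are the 10 with the largest change in each direction for giant against control cells, and the 8 for the kits, for which all samples of a group lay beyond all samples of the other within each kit or cell type. For contrasts within 1 kit or 1 cell type, the 3 largest in each direction are named. From each list the 4 members with the smallest adjusted p are named in part, or all members where 5 or fewer were measured. Members called measured are those kept by the filter, so dimmer members of a list or family are left out.

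Gene lists numbered 24, with 337 nuclear genes and the organelle genomes. Only 56 of the 337 genes were named on the array and 34 kept, because many probe sets are not listed with a gene. With a minimum of 3 kept members, 7 lists were tested: wall loosening, peroxidases, auxin, cytoskeleton, cytosolic ribosomal proteins, and the genes of the chloroplast and mitochondrial genomes. Another 6 lists had 1 or 2 kept genes, given as single values, and 11 had 0 and were not tested. Those 11 were the mitotic cell cycle, jasmonate, cytokinin, aquaporins, sugar and amino acid transport, heat shock, and the markers of phloem, endodermis, root hairs, stele and root meristem, so no list of another root cell type could be read. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A set of 19 gene families, formed from gene symbols, was added after the data had been seen.

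Array measures (3'/5' signal ratios, rRNA signals and the shape of the signal distribution) were compared with exact two-sided permutation tests, permuting kit within cell type or cell type within kit (400 arrangements, smallest possible p 0.005). The 18 tests were adjusted together. The fit was tested on simulated data with 200 of 14652 probe sets changed, drawn with a spread of its own for each kit. Most contrasts called more than 200 probe sets in the real data, and each share below comes from 1 draw. Recovered and false shares both depend on how many probe sets change, so they describe that simulation only. With a true log2 change of 2, 67% were recovered for giant against control cells over both kits, 47% in One-Direct and 30% in Pico. The same share was 72% for the kits over both cell types, 25% in control cells, 28% in giant cells and 0% for the difference of effects between kits. Of the calls in that simulation, 12.2% were false for giant against control over both kits, 52.7% in One-Direct, 0% in Pico and 4.4% for the kits over both cell types. In control cells 16.7% of the kit calls were false, and in giant cells 11.4%. For the difference of effects between kits, 1 call was made in that simulation and it was false.

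Alternatives were a pseudocount of 1 or 64, no filter, a filter at the 75th percentile, quantile normalisation, the first technical array only, all 20 arrays with the sample as a random block, sample quality weights, a fit of the compared groups only, the replicate number as a block, and each sample left out in turn. Median centring, a weight per kit, the omission of 2 samples together, and further control probe sets were added after the data had been seen. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.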

Results

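Gene expression was measured on 20 arrays of laser-captured giant cells and control root cells, amplified with the One-Direct or the Pico kit (4 groups, 3 biological samples each). The design asks which genes differ between giant and control cells and how far the answer depends on the kit. Cell type goes with the amount captured (about 80 giant or 150 control cells per sample), so these cannot be told apart. No marker list of another root cell type could be read, so the make-up of the control samples was not checked. Genes said to rise or fall in giant cells therefore differ between these captured samples, whatever the reason. All arrays shared a trimmed mean signal of about 500, and their median signals ran from 166.5 to 311.3. The first principal component, with 45.8% of the variance, parted the kits. The second, with 20.4%, parted giant from control cells within each kit.

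**Figure D1:**
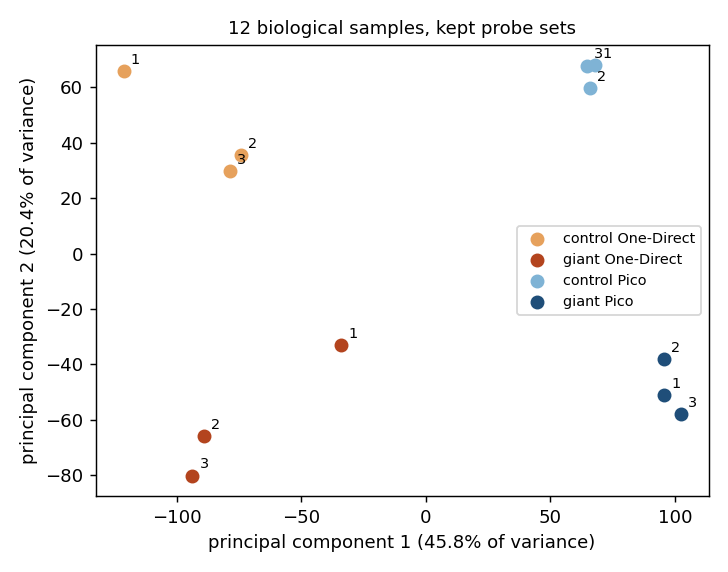
Principal components 1 (45.8% of the variance) and 2 (20.4%) of log2 signal over 14652 probe sets, 1 point per biological sample, n = 3 per group. One-Direct samples lie at negative and Pico samples at positive values of component 1, and giant cells lie at negative and control cells at positive values of component 2.

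Signals of One-Direct samples had a larger median SD than those of Pico samples at both levels of replication, a difference described here without a test. The median SD over 3 technical arrays was 0.647 log2 units for control cells with One-Direct and 0.285 with Pico, and 0.389 and 0.288 for giant cells. Over 3 biological samples, each as 1 array, the median SD was 0.774 against 0.386 for control cells and 0.50 against 0.347 for giant cells. The ratio of One-Direct to Pico was 2.27 in control and 1.35 in giant cells for technical spread, and 2.00 and 1.44 for biological spread (geometric means 1.75 and 1.70). Biological samples correlated across probe sets with a mean r of 0.662 (control) and 0.738 (giant) in One-Direct and of 0.904 and 0.931 in Pico. Control One-Direct sample 1 stood apart, with r of 0.649 and 0.587 to the other samples of its group, which correlated with each other at 0.784. Giant One-Direct sample 1 lay apart as well: it correlated at 0.77 and 0.724 with its group, whose other 2 samples correlated at 0.823, and at 0.766 with giant Pico sample 1 and 0.758 with control One-Direct sample 2. On component 1 it lay at -33.9, against -89.2 and -93.8 for its group. The mean r of each group takes 1 array per sample, while the r of single pairs averages technical arrays. Giant One-Direct sample 1, giant Pico sample 1 and control One-Direct sample 2 were split samples, and averaging can raise their r. With 1 array per sample, the lowest r among giant One-Direct samples was 0.671.

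With all arrays scaled to a common mean, the changes given here are relative to the array and are not amounts per cell. AGL24 (AT4G24540), a MADS-box transcription factor known from flowering, had a 19.4-fold higher signal in giant than in control cells (log2 change 4.28, SE 0.54, adjusted p = 0.000271, limma, n = 3 per group). Its mean log2 signal went from 6.58 ± 1.23 (SD) to 10.67 ± 0.68 in One-Direct and from 6.67 ± 1.68 to 11.12 ± 0.06 in Pico. NRT2.5 (AT1G12940), a high-affinity nitrate transporter, was 10.5-fold higher, and HAT2 (AT5G47370), an auxin-responsive homeodomain transcription factor, 8.89-fold. BGLU28 (AT2G44460), a beta-glucosidase, rose 8.45-fold, NGA1 (AT2G46870), a B3 transcription factor, 7.70-fold, and AT2G21130, a cyclophilin, 7.55-fold. AT3G28500, an acidic ribosomal protein P2, rose 8.22-fold over both kits, with a log2 change of 4.68 in Pico and 1.40 in One-Direct (adjusted p = 0.075 there). The other genes named as higher were AT3G20180 (13.7-fold), AT4G21323 (10.8-fold) and AT1G20120 (8.46-fold). For these 3, NRT2.5 and AT3G28500, control cells had a mean signal of about 16, the pseudocount, or less in at least 1 kit, so their folds and ranks depend on it. Over the settings their log2 changes ran from 2.50 to 5.12 (AT3G20180), 2.31 to 4.51 (AT4G21323), 1.93 to 4.35 (AT1G20120), 2.58 to 4.06 (NRT2.5) and 2.21 to 3.63 (AT3G28500). Adjusted p of these 10 genes ran from 4.13e-05 to 0.00189.

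AT3G01260 was 23.2-fold lower in giant cells (log2 change -4.54, SE 0.34, adjusted p = 2.44e-05, limma, n = 3 per group). BCAT4 (AT3G19710), which acts in methionine chain elongation for glucosinolates, was 19.8-fold lower (log2 change -4.30, SE 0.58). MSRB9 (AT4G21850), a methionine sulfoxide reductase, was 17.7-fold lower, SBT4.12 (AT5G59090), a subtilase, 16.7-fold, AT1G30760, a berberine bridge enzyme-like protein, 14.8-fold, and the kinase WNK9 (AT5G28080) 14.6-fold. The rest of the 10 were AT4G36500 (18.8-fold), AT4G27654 (18.0-fold), AT3G53980 (16.8-fold) and AT5G08240 (15.5-fold). By the rule that named these 20 genes, every giant cell sample lay beyond every control sample within each kit. AT3G01260 had a mean signal of 5.04 in giant cells with Pico, below the pseudocount of 16, and its log2 change ran from -5.92 to -3.32 over the settings, so its size and rank depend on the pseudocount.

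**Figure D2:**
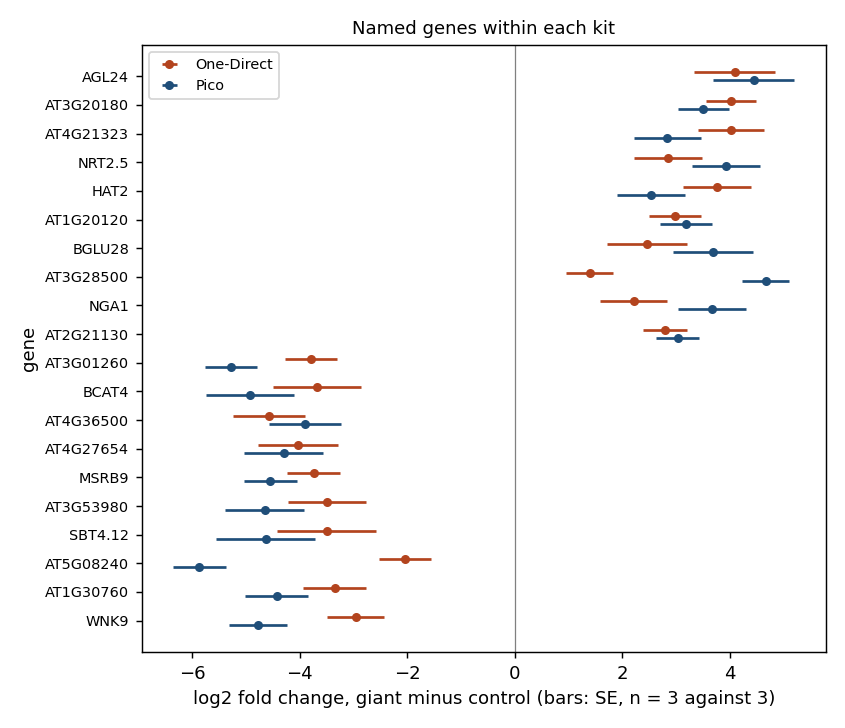
Log2 fold change of giant over control cells for the 20 named genes, with its standard error, drawn separately for One-Direct and Pico (n = 3 samples per group). AGL24 changed by 4.10 in One-Direct and 4.45 in Pico, and AT3G28500 by 1.40 and 4.68.

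Among the lists, the 3 peroxidases kept by the filter, of 8 named on the array, fell in giant cells (camera, adjusted p = 0.00427, and 0.149 with an estimated correlation). All 3 also passed when adjusted over the list alone. Their median log2 change was -2.28 relative to the median of all probe sets. AT3G21770 changed by -2.04 (adjusted p = 0.00137), AT4G30170 by -2.10 (adjusted p = 0.0259) and AT3G01190 by -1.38 (adjusted p = 0.0469). For AT4G30170 the change was -4.54 in Pico and 0.35 in One-Direct, and for AT3G01190 it was -3.39 and 0.64. AT3G01190 lost its call in 15 of 23 other settings, and AT4G30170 in 3 of 24.

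Of 9 wall-loosening genes, EXLA1 (-1.84) and EXLA3 (-3.60), which are expansin-like, fell, and AT3G27400, a pectate lyase-like gene, rose (1.47), with the same 3 calls adjusted over the list alone. As a list they did not pass (adjusted p = 0.05001; adjusted p = 0.398 with an estimated correlation), and AT3G27400 lost its call in 16 of 23 other settings. Of 5 auxin genes IAA29 rose (1.71, limma adjusted p = 0.0187, call lost in 2 of 22 other settings). Of 6 cytoskeleton genes the formin AT3G07540 rose (1.58, limma adjusted p = 0.0156, call lost in 3 of 24 other settings). Neither list passed (adjusted p = 0.424 and 0.937); adjusted over the list alone, 1 auxin gene rose, and 1 cytoskeleton gene rose and 1 fell. None of 4 cytosolic ribosomal protein genes passed by limma over all probe sets or adjusted over the list alone (list adjusted p = 0.91). Single genes of lists too small to test included WRKY53, a transcription factor of the defence list, which fell by 3.41 (SE 0.47, adjusted p = 0.000484), and the dehydrin COR47, which fell by 1.58 (adjusted p = 0.0015). PRL, a replication licensing factor (0.83, adjusted p = 0.189), GUT2 of the xylem wall list (-0.13, adjusted p = 0.813), HCT of the lignin list (-1.23, adjusted p = 0.106), and RCA (0.76) and PSAE-1 (0.83) of photosynthesis (adjusted p = 0.254 and 0.257) did not pass.

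The 67 chloroplast-encoded genes passed as a list in the lower direction (camera, adjusted p = 0.0034; adjusted p = 0.684 with an estimated correlation), with a median of -0.44 relative to all probe sets. Only psbC (-0.75) and psbZ (-0.72) passed singly, with calls lost in 10 and 14 of 24 other settings, 0 genes passed adjusted over the list alone, and with quantile normalisation the list did not pass (adjusted p = 0.687). The 14 mitochondrial genes did not pass (adjusted p = 0.118), nor did any member over all probe sets or adjusted over the list alone. Beside these groups, an array measure of RNA ends differed between the cell types: the log2 3'/5' ratio of the GAPDH control probe sets was 1.17 lower in giant than in control cells (exact permutation test, two-sided, adjusted p = 0.015). It averaged 3.46 ± 1.02 (SD, n = 3) in control and 2.27 ± 0.179 in giant cells with One-Direct, and 2.34 ± 0.204 and 1.2 ± 0.158 with Pico. A further pair of GAPDH probe sets, added after the data had been seen, differed by -0.271 (exact permutation p = 0.355), and the actin and ubiquitin ratios did not differ detectably (adjusted p = 0.611 and 0.995). The share of summed signal in the brightest 1% of probe sets was 3.38 percentage points lower in giant cells (exact permutation, adjusted p = 0.0386).

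Over both kits, 2868 of 14652 probe sets passed between giant and control cells, 1544 higher and 1324 lower in giant cells (53.8% higher). The median of all probe sets was shifted by 0.24 log2 units, and the share of higher calls was 42.3% with quantile normalisation and 38.5% with median centring, so the balance of directions depended on the scaling. Without giant Pico sample 1 the count was 1856 and without giant Pico sample 3 it was 1808, while sample quality weights gave 4335 and the stricter filter 1851.

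In One-Direct alone, AGL24 rose (log2 change 4.10, adjusted p = 0.0117), as did AT3G20180 (4.03, adjusted p = 0.00323) and AT4G21323 (4.03, adjusted p = 0.00664). AT4G36500 (-4.57, adjusted p = 0.00624), AT2G44500 (-4.29, adjusted p = 0.00289) and AT4G27654 (-4.03, adjusted p = 0.0115) fell. Each of these calls was lost in 1 to 4 of its other settings, and over them the log2 change ran from 2.63 to 5.71 for AT3G20180 and from 2.75 to 5.29 for AT4G21323. In all, 826 probe sets passed with limma, 518 higher and 308 lower (62.7% higher; 40.4% with quantile normalisation, 40.8% with median centring, 44.2% with the stricter filter and 51.6% with sample quality weights). These calls rest on a spread shared with the less variable Pico samples: with only the compared samples in the fit, 0 probe sets passed, with 3607 at an unadjusted p under 0.05 in the shared fit, and with a weight per kit 10 passed, 2 of them higher. The median residual SD was 0.699 in One-Direct and 0.378 in Pico. In 1 simulated draw with such a difference, where only 200 probe sets were changed, 59 of 112 calls were false. Without giant One-Direct sample 2 or 3 the counts were 190 and 197, without giant Pico sample 1 or 3 they were 493 and 535, and without control One-Direct sample 2 or 3 they were 1432 and 1359. Leaving out sample 1 of both One-Direct groups, a choice made after seeing the correlations, gave 1720, and the first technical array alone gave 463.

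In Pico alone, AT3G28500 rose (log2 change 4.68, adjusted p = 0.000113), with AGL24 (4.45, adjusted p = 0.00271) and NRT2.5 (3.93, adjusted p = 0.00201). AT5G08240 fell by 5.87 (adjusted p = 0.000107), AT5G28630 by 5.58 (adjusted p = 0.00145) and SWEET11 (AT3G48740), a sucrose transporter, by 5.50 (adjusted p = 0.000641), each on the log2 scale. With Pico signals near the pseudocount in 1 cell type, AT3G28500 ran from 3.42 to 5.66, NRT2.5 from 2.72 to 5.07 and SWEET11 from -7.10 to -4.16 over the settings. With limma 1391 probe sets passed, 356 higher and 1035 lower (25.6% higher). The count was 3056 with only the compared samples in the fit (43.3% higher), 3487 with a weight per kit (43.6%), 4101 with sample quality weights (47.9%), 746 with quantile normalisation (24.5%) and 2505 without sample 1 of both One-Direct groups (35.9%). It was 725 and 727 without giant Pico sample 1 or 3, 886 and 789 without control Pico sample 1 or 3, and 2293 without control One-Direct sample 1.

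Both kits ordered giant cell changes alike in part. Across the 14652 probe sets, which are not independent replicates, the log2 changes measured with the 2 kits correlated at r = 0.596 (Spearman's rho 0.514), and 70.5% had the same sign (66.9% relative to the medians). The 2 contrasts compare different samples, but their calls rest on 1 shared estimate of the spread per probe set. The 2 lists of calls are therefore not independent even without agreement, and the One-Direct calls were lost with only the compared samples in the fit. Of the called probe sets, 335 were called with both kits, 334 of them in the same direction. Of these, 97 were higher with both, where independent lists would share 12.6, and 237 were lower, where they would share 21.8. Because of the shared spread, the excess over these values is not by itself a measure of agreement. Among Pico calls 87.2% had the same sign in One-Direct, and among One-Direct calls 96.5% had the same sign in Pico.

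Between the kits, most of the 8 genes named as higher in One-Direct were annotated pseudogenes, dim in Pico. AT3G30670 was 195-fold higher (log2 change 7.61, SE 0.32, adjusted p = 9.07e-09, limma, n = 3 per group) and AT2G06480 191-fold (log2 change 7.58, SE 0.33). In Pico the mean signal of AT3G30670 was 3.36 in control and 3.52 in giant cells, below the pseudocount of 16, so its fold depends on the pseudocount, and its log2 change ran from 5.84 to 9.79 over the settings. AT1G36550 (156-fold, log2 change 5.67 to 8.998 over the settings), AT3G32020 (133-fold, 5.61 to 8.33), AT4G04010 (114-fold, 5.42 to 8.19), AT4G05640 (113-fold, 5.58 to 7.82) and AT1G32840 (101-fold, 5.17 to 8.06) are also annotated as pseudogenes, while AT1G49680 (95.9-fold, 5.07 to 8.06) is protein-coding. These 6 also had Pico signals under 16 in at least 1 cell type, so their folds and ranks depend on the pseudocount as well. The probe sets of AT3G30670 and AT2G06480 carry the suffix _s_at, and those of AT3G32020, AT4G04010, AT1G32840 and AT1G49680 the suffix _x_at. Such suffixes mark probe sets that may match transcripts of other genes, so these folds may not be specific to the gene named. Lower in One-Direct were cytosolic ribosomal protein genes: AT4G29410 by 11.4-fold (log2 change -3.51, SE 0.27, adjusted p = 6.56e-07), AT3G11510 by 10.1-fold, AT2G19730 by 7.47-fold and AT3G53430 by 6.63-fold. HTB2 (AT5G22880), a histone H2B, was 7.77-fold lower and AT1G04680, a pectin lyase-like gene, 8.08-fold, with AT4G38710 (7.08-fold) and AT1G64370 (7.03-fold).

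The lists of 4 ribosomal protein genes and 6 cytoskeleton genes passed in the lower direction in One-Direct relative to Pico (camera, adjusted p = 0.00692 for each; adjusted p = 0.259 for each with an estimated correlation). Of the ribosomal genes 3 fell, with AT3G09200 at -2.27 and AT3G09630 at -1.53, and 4 did so adjusted over the list alone. Tubulins made up most of the cytoskeleton calls: TUA6 (-1.62), TUB5 (-1.55), TUB6 (-1.40) and TUB7 (-0.93) were among the 5 that fell, also adjusted over the list alone. Neither list was matched on signal. The 4 ribosomal genes were bright, with mean log2 signals of 12.5 to 13.82 in Pico control cells. Protein-coding probe sets above a signal of 100 in Pico had a median kit difference of -0.208. The median was -1.90 for the ribosomal and -1.32 for the cytoskeleton list. Part of the fall may go with brightness, which was not tested. The wall list did not pass (camera, adjusted p = 0.616), with EXPA16 higher (2.52) and EXPB3 (-1.67), AT3G27400 (-1.49) and EXPA4 (-1.49) lower. EXPA4 lost its call in 5 of 24 other settings and AT3G27400 in 2 of 23. IAA20 (2.52) and IAA29 (2.16) rose in the auxin list (adjusted p = 0.257), and no peroxidase passed (list adjusted p = 0.944). Among 67 chloroplast genes 17 rose, such as ndhK (1.81) and petL (1.63), and 9 fell, such as psaI (-2.05), with a list adjusted p of 0.616. Of 14 mitochondrial genes 1 rose and 4 fell, such as nad1 (-1.82), with a list adjusted p of 0.419. For each of these lists the counts adjusted over the list alone were the same. GUT2 was higher (1.30, adjusted p = 0.0073), and COR47 (-1.22, adjusted p = 0.00269) and PSAE-1 (-2.25, adjusted p = 0.00341) were lower in One-Direct; PRL (-1.08), HCT (-0.30), RCA (-0.63) and WRKY53 (0.12) did not pass.

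The array measures moved with the kit as well. Signal of the 5S rRNA control was higher in One-Direct (log2 difference 6.77) and that of 25S rRNA lower (log2 difference -2.08), with adjusted p = 0.015 for both by exact permutation. In Pico the log2 5S signal, computed without a pseudocount, was low, between 4.22 and 6.76. It varied between samples there (SD 1.43 in control cells), so the exact size of that difference is uncertain. The bioB hybridisation control, which does not come from the sample and was looked at later, was also lower in One-Direct (log2 difference -1.31, exact permutation p = 0.02), so the scaling of the arrays is not excluded for the 25S difference or part of it. The GAPDH 3'/5' ratio was 1.09 log2 units higher in One-Direct (adjusted p = 0.015, exact permutation), while actin (-0.259, adjusted p = 0.367) and ubiquitin (0.125, adjusted p = 0.799) did not differ detectably. The further probe sets added later gave 0.705 for GAPDH (exact permutation p = 0.01) and -0.864 for actin (exact permutation p = 0.005), so the end ratios did not move in 1 direction. The interquartile range of log2 signal was lower by 0.744 and the share of signal in the brightest 1% of probe sets by 7.43 percentage points (adjusted p = 0.015 for each, exact permutation). The share of probe sets at or above 0.2 of the trimmed mean was 11.1 points higher in One-Direct (adjusted p = 0.04, exact permutation), at 65.2% and 78.3% for control and giant cells against 62.6% and 58.9% in Pico.

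**Figure D3:**
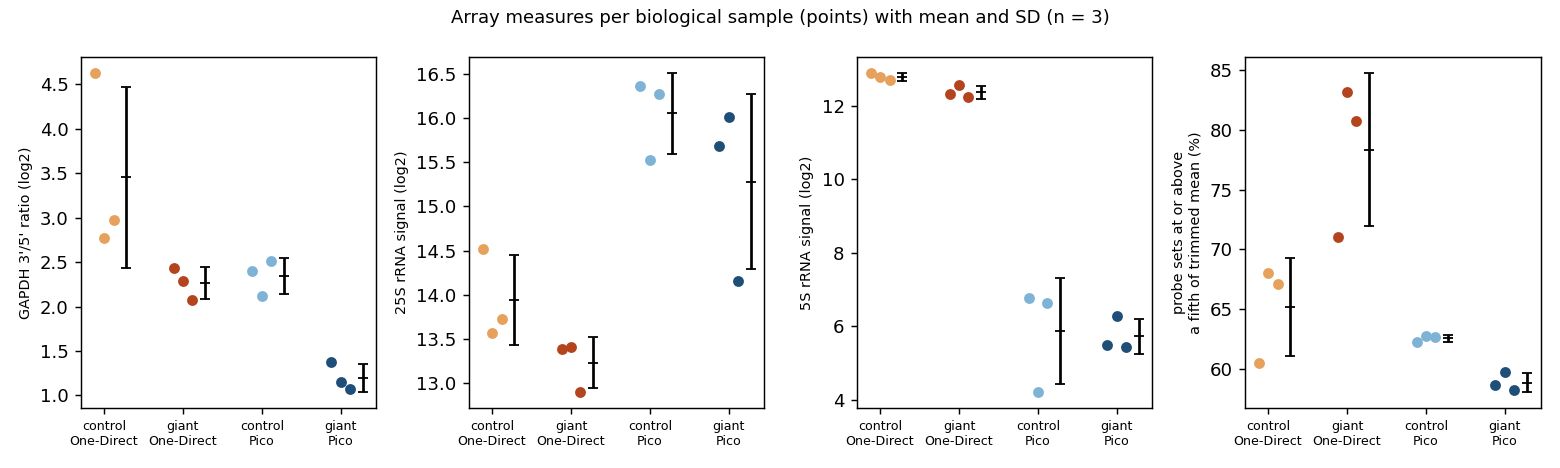
Array measures per biological sample (points) with the mean and SD of each group (n = 3): log2 3'/5' ratio of GAPDH, log2 signal of 25S and 5S rRNA, and percent of probe sets at or above 0.2 of the trimmed mean. The 5S rRNA signal averaged 12.8 and 12.4 in One-Direct and 5.87 and 5.73 in Pico for control and giant cells.

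Over both cell types 5027 probe sets passed between the kits, 2635 higher and 2392 lower in One-Direct (52.4% higher; 43.2% with quantile normalisation and 44.3% with median centring). Without a filter on dim probe sets the count was 8220 (69.8% higher) and with the stricter filter 2969 (38.2% higher), of 22746 and 7893 tested. In control cells AT2G06480 (8.97), AT3G30670 (7.59) and AT4G05640 (7.43) had the largest positive log2 changes, and AT1G52070, a jacalin-type lectin (-4.14, adjusted p = 0.000217), AT1G09750 (-3.99, adjusted p = 0.014) and AT1G04680 (-3.95, adjusted p = 0.00395) the largest negative ones. There 3123 probe sets passed, 1647 higher and 1476 lower, with 2062 without control Pico sample 1, 1701 with only the compared samples in the fit (66.9% higher) and 1907 with the stricter filter (42.4% higher). In giant cells the largest log2 changes were those of AT3G30670 (7.63), AT1G36550 (7.63) and AT4G04010 (6.89), and of AT4G29410 (-3.28), AT3G11510 (-3.03) and AT5G01210 (-2.99, adjusted p = 9.69e-05). The changes of AT3G30670 ran from 5.81 to 9.80 in control and from 5.86 to 9.78 in giant cells over the settings, so sizes and ranks of such dim genes depend on the pseudocount here too. In giant cells 3099 passed, 2222 higher and 877 lower (71.7% higher; 54.8% with quantile normalisation and 58.2% with median centring). That count was 6178 without a filter (85.4% higher), 1708 with the stricter one (49.1%), 5838 with sample quality weights (55.8%) and 4666 without sample 1 of both One-Direct groups. The kit difference correlated between control and giant cells at r = 0.785 (rho 0.677) across probe sets, and 1834 of 1845 probe sets called in both had the same direction.

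The giant cell change of AT1G52070, the lectin gene, differed between the kits by 5.43 log2 units (SE 0.78, adjusted p = 0.0471, limma, n = 3 per group), and by 3.68 to 7.07 over the settings. Its mean log2 signal was 9.27 in control and 5.02 in giant cells with Pico, a change of -4.25 (adjusted p = 0.000584), and 5.13 and 6.31 with One-Direct, a change of 1.18 (adjusted p = 0.208). Another 2 probe sets passed, neither listed with a gene, with differences of 4.14 (adjusted p = 0.0471) and 5.18 (adjusted p = 0.0382). Of the lists, the peroxidases differed in the higher direction (camera, adjusted p = 0.00103; adjusted p = 0.0941 with an estimated correlation), with AT3G01190 at 4.03, AT4G30170 at 4.89 and AT3G21770 at 0.91. None of these 3 passed over all probe sets by limma and 2 did adjusted over the list alone. Chloroplast genes (adjusted p = 0.00103; adjusted p = 0.472 with an estimated correlation) and mitochondrial genes (adjusted p = 0.00017; adjusted p = 0.461 with an estimated correlation) differed in the lower direction, with 0 members passing over all probe sets or adjusted over the list alone. The chloroplast direction turned with quantile normalisation (adjusted p = 0.275). The wall, auxin, cytoskeleton and ribosomal lists did not pass (adjusted p = 0.26, 0.126, 0.609 and 0.75), with 0 members passing over all probe sets and 1 cytoskeleton gene adjusted over the list alone.

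Across all probe sets 3 passed this test, with 1347 at an unadjusted p under 0.05, and in simulated data it recovered 0% of true log2 differences of 2, and its 1 call there was false. The count was 0 with a pseudocount of 1 or 64, no filter, quantile normalisation or the first technical array, and 1 with the stricter filter. It was 29 with all arrays and the sample as a random block, and 32 with sample quality weights or without sample 1 of both One-Direct groups. It was 0 without control One-Direct sample 3, giant One-Direct sample 2 or 3, giant Pico sample 1 or 3, or any control Pico sample. It was 53 without control One-Direct sample 2, 9 without giant Pico sample 2 and 2 without control One-Direct sample 1.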

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

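The omission of 2 One-Direct samples together was chosen only after the result had been seen. In the main fit, 3 probe sets passed a test of whether their giant cell change differed between the 2 kits. These calls changed with the setting, as given below. AT1G52070, a lectin gene, differed by 5.428 log2 units (adjusted p = 0.0471, limma), with a change of 1.18 in One-Direct and -4.25 in Pico. A probe set not listed with a gene differed by 4.136, with changes of 1.26 (adjusted p = 0.0895) and -2.87 (adjusted p = 0.00116). Another unlisted one differed by 5.175, with changes of 0.99 (adjusted p = 0.213) and -4.19 (adjusted p = 0.000267). In each of the 3, the Pico control samples were bright and the Pico giant cell samples dim, while the One-Direct change did not pass.

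Control One-Direct sample 1, which correlated least with its group, was weighed as the source of this difference. Without it the median difference of the 3 probe sets was 5.13, which is 0.991 of its value with the sample. These probe sets had SDs of only 0.61, 0.75 and 0.5 in that group, so leaving out 1 sample could move the difference little. The ratio therefore shows that the size held without the sample, but could hardly have come out otherwise. In 100 of the 200 distinct splits of the samples within each kit, made after the giant cell effect shared by the kits had been taken out, 1 gave as many calls, the real one with 3, and the highest count in another split was 1. The real split thus gave the most calls in this setting, but by a margin of only 2 calls. The count was 0 with a pseudocount of 1 or 64, no filter or quantile normalisation, so that margin is too thin to exclude chance. Which probe sets pass is less settled: AT1G52070 lost its call in 16 of 23 other settings (highest adjusted p 0.393), while 32 probe sets passed without the pair of One-Direct samples. Unequal capture of these transcripts by the kits and a real difference between the captured cells both stay open, since each kit had samples of its own. A raised floor of dim probe sets in One-Direct was not tested for these 3 and stays open too. In giant cells 78.3% of probe sets lay at or above 0.2 of the trimmed mean with One-Direct, against 58.9% with Pico. The One-Direct means (control and giant, log2) were 5.13 and 6.31 for AT1G52070, and 6.44 and 7.71, and 8.63 and 9.62, for the unlisted probe sets. No biological explanation was tested.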

How the results depend on the processing

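A weight per kit and the omission of sample 1 of both One-Direct groups were chosen only after the results had been seen, as was median centring. The fits assume 1 spread for both kits, which was not so, and this limits the comparisons within 1 kit most. Of the alternative values of 93 results on named genes, 2135 kept their side of the threshold, 100 no longer passed and 0 changed direction. All 93 had passed in the main fit, many of them picked for the largest changes. None could therefore come to pass, a change of direction was unlikely, and the tally does not describe other genes. Among the array measures 201 kept their side, 22 no longer passed, 3 came to pass and 8 changed sign, all 8 for differences that had not passed. Dim probe sets set the limit of signal over background, and leaving out the filter moved each count for the kits by more than any count for giant vs control. Unless stated, the cause was not tested.

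With the stricter filter, which tests 7893 probe sets, the counts were 1851 (giant vs control, both kits), 2969, 1907 and 1708 (One-Direct vs Pico in both cell types, control cells and giant cells) and 1 (kit by cell type interaction). With no filter they were 8220 and 6178 (both cell types, giant cells) and 0 (interaction). Quality weights gave 4335 and 4101 (giant vs control, both kits and Pico), 5838 (kits in giant cells) and 32 (interaction). With only the 2 compared groups fitted, the counts were 0 (giant vs control, One-Direct, with 3607 at an unadjusted p under 0.05 in limma's shared fit), 3056 (Pico) and 1701 (kits in control cells). The weight per kit gave 10 in One-Direct and 3487 in Pico, a setting built to let the spread of the kits differ. Without the pair of doubted samples the counts were 1720 (One-Direct), 2505 (Pico), 4666 (kits in giant cells) and 32 (interaction). Quantile normalisation gave 746 (Pico) and 0 (interaction), and the first technical array 463 (One-Direct) and 0 (interaction). The interaction count was 0 with a pseudocount of 1 or 64, against 3 with 1347 at an unadjusted p under 0.05 in the limma fit, and 29 with all arrays and the sample as a random block.

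With single samples left out in turn, counts ran from 1808 to 3812 (giant vs control, both kits), 190 to 1432 (One-Direct), 725 to 2293 (Pico), 2062 to 3553 (kits in control cells) and 0 to 53 (interaction). Lists past the threshold, giant vs control, numbered 2 in camera, 2 to 4 with samples left out, 0 with an estimated correlation, 1 with fry, 1 with quantile normalisation and 4 without the doubted pair. With an estimated correlation 0 lists passed for the kits or the interaction, and with fry 1 for the interaction. The correlation of giant cell changes between kits was 0.551 and 0.632 with a pseudocount of 1 and 64, 0.489 without a filter, 0.691 with the stricter one, 0.632 with quantile normalisation, and 0.496 to 0.616 with samples left out. The ratio of biological spread was 2.101 with quantile normalisation. The ubiquitin 3'/5' difference, which did not pass, ran from -0.198 to 0.331 between kits and from -0.202 to 0.327 between giant and control cells with samples left out, and was -0.054 for the latter with the first technical array. Of 9 array measures, 2 passed between giant and control cells, and 1 to 4 with samples left out.

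The replicate number as a block gave 2748, 751 and 1307 calls for giant vs control (both kits, One-Direct, Pico), 4912, 2962 and 2988 for the kits (both cell types, control, giant) and 2 for the interaction. Deviations of same-numbered samples from their group means correlated between -0.064 and 0.138 over 18 pairs, with 1 over 0.1, the minimum set for a pairing. This did not show a pairing by number, and with so few samples per group it cannot exclude one.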

Other observations

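Tests of gene families, of pseudogene probe sets above a signal of 100 and of the further settings were chosen only after the data had been seen. Among 19 families formed from gene symbols, autophagy genes rose in giant cells: of 7 measured, ATG8C (log2 change 1.62, SE 0.27), ATG8D (1.53), ATG8B (1.41) and ATG8G (1.28) passed (camera, family adjusted p = 0.00986; adjusted p = 0.0917 with an estimated correlation). Sugar transporters of the SWEET family fell, with SWEET11 (-3.73, SE 0.51), SWEET16 (-1.74) and SWEET17 (-1.61) of 4 measured (family adjusted p = 0.00497; adjusted p = 0.076 with an estimated correlation). Xyloglucan-modifying XTH18 (-2.65), XTH19 (-1.63) and XTH32 (-1.21) of 4 fell (family adjusted p = 0.0119; adjusted p = 0.076 with an estimated correlation), although XTH32 changed by 0.12 in One-Direct (adjusted p = 0.913) and -2.54 in Pico (adjusted p = 0.0105), and XTH19 by -0.45 (adjusted p = 0.629) and -2.81 (adjusted p = 0.00505). Of 10 RALF-like peptide genes RALFL32 (-3.62) and RALFL22 (-3.35) fell (family adjusted p = 0.0187; adjusted p = 0.076 with an estimated correlation). Of 25 UDP-glycosyltransferases UGT72E2 (-1.91), UGT74B1 (-1.65) and UGT73B5 (-1.12) fell (family adjusted p = 0.00986; adjusted p = 0.076 with an estimated correlation), and of 9 glutathione transferases 4 fell, such as GSTF4 (-2.80), while GSTL3 rose by 1.24 (family adjusted p = 0.0161; adjusted p = 0.076 with an estimated correlation). Of the 4 that fell, GSTU23 changed by -0.06 (adjusted p = 0.957) and GSTU22 by 0.22 (adjusted p = 0.824) in One-Direct, against -2.59 (adjusted p = 0.00763) and -2.58 (adjusted p = 0.00635) in Pico. The log2 3'/5' ratio of GAPDH was 1.17 lower in the same giant cell samples, while the actin and ubiquitin ratios did not differ detectably. The further GAPDH pair added later differed by -0.271 (exact permutation p = 0.355).

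The families first also held SWEETIE and the cyclophilins CYP59 and CYP71, which share only a name with them, and these 3 were taken out after the results had been seen. With them in, the 6 families above passed. Without them 10 did, the added 4 being cytochromes P450 (family adjusted p = 0.0187, 2 of 8 members lower, such as CYP71B26 at -2.47), carboxypeptidase-like genes (family adjusted p = 0.0474, 3 of 10 lower, such as scpl48 at -2.53), tetraspanins (family adjusted p = 0.044, 3 of 6 lower, such as TET8 at -2.03) and RNA polymerase subunits with Sm-like genes (family adjusted p = 0.0474, 5 of 17 higher, such as NRPC2 at 1.46). With those 3 symbols in, these 4 had camera adjusted p of 0.0928, 0.0526, 0.0503 and 0.0526, so they rest on that correction. Over 21 other settings the cytochromes P450 passed in 19, the carboxypeptidase-like genes in 12, the tetraspanins in 13, and the RNA polymerase and Sm-like genes in 10. With an estimated correlation 0 families passed under either form. Other symbols of doubtful membership were left in, such as LSMT-L in the last of these and PDF1A and PDF1B among the defensin-like genes, which did not pass (adjusted p = 0.738). For the kits, the histone family passed in the lower direction in One-Direct (family adjusted p = 0.0433, and 0.481 with an estimated correlation), with 3 of 5 members lower (HTB2 at -2.96, HTB4 at -1.80, HTB11 at -1.10). This family was not matched on signal. For the interaction, in the higher direction, glutathione transferases passed in both forms (camera, family adjusted p = 0.00105, and 0.0576 with an estimated correlation). SWEET genes passed in the corrected form (camera, family adjusted p = 0.0209, against 0.0685 with the 3 symbols in, and 0.153 with an estimated correlation). Of their members 0 of 9 and 0 of 4 passed over all probe sets, and 3 of each did so adjusted over the list alone. Over 21 other settings the glutathione transferases passed in 20 and the SWEET genes in 14.

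Pseudogene probe sets were brighter in One-Direct, a pattern noticed among the named genes: of 332 kept, 312 were higher and 2 lower, against 1356 higher of 7768 protein-coding ones, although the filter favours probe sets bright in either kit. Over all 923 on the array the median kit difference exceeded that of 12443 protein-coding probe sets by 1.84 (95% bootstrap interval 1.73 to 1.94), as genomic DNA copied along with RNA in One-Direct would give and as a raised floor of dim probe sets may give too. Matched on Pico signal in 20 bins the excess was 0.649 (0.535 to 0.814), above the 0.5 set beforehand as evidence against a raised floor, but after seeing this value the floor was kept open, because only 37 pseudogene probe sets lay above a signal of 100 in Pico and dim probe sets cannot exclude it. Above that signal the matched excess was 0.395 (0.00919 to 1.62), which decides nothing. The matched excess in giant cells minus that in control cells was -0.0893 (-0.197 to 0.0651). Before matching, the median kit difference in giant cells was 2.55 for pseudogene and 0.423 for protein-coding probe sets. In control cells these medians were 1.71 and 0.0185, a narrower gap. Whether giant cells brought more DNA is therefore also undecided, and a biological source was not tested.

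Calls between giant and control cells leaned higher in One-Direct (62.7% higher) and lower in Pico (25.6%), a gap of 37.1 percentage points. With quantile normalisation the gap was 15.9 points, between the 10 that would point to scaling of arrays with an unequal dim end as the main cause and the 25 that would speak against it. With sample quality weights the shares were 51.6% and 47.9%, and with a weight per kit 20% (of 10 calls) and 43.6%, so the gap also depended on how the unequal spread of the kits was treated. The scaling and the spread may therefore each account for part of the gap, and the rest stays open, as a difference between the captured cells was not tested.

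For the number of calls, chance can be excluded for giant against control cells over both kits (2868, with 519 as the highest of the other splits) and for the kits over both cell types (5027, with 532), each with 1 of 100 splits as large. Within 1 kit or 1 cell type the 10 splits are too few for a share under 0.05: the real counts were 826 (One-Direct), 1391 (Pico), 3123 (control cells) and 3099 (giant cells), 1 of 10 in each, and the highest other count was 0.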
